A study of Homo sapiens with 35 samples.

How the data were processed

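Gene expression was measured in BE(2)-C cells, a human neuroblastoma cell line, on 35 Affymetrix arrays of a human whole-genome design in its early access version, hybridised with biotin-labelled cRNA primed from oligo-dT. Cells received DMSO (the vehicle), all-trans retinoic acid at 5 uM (ATRA), the histone deacetylase inhibitor valproic acid at 1 mM (VPA) or both, and were collected at 6 h, 24 h and 72 h. The 12 groups held 3 arrays each, except DMSO at 72 h, which held 2. The labels call the replicates triplicates and say nothing of separate days or passages. Each p-value therefore measures the spread between these samples, pooled over all 12 groups.

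The deposited values are intensity on a linear scale, summarised per probe set and normalized by the authors with RMA, per the submitters' processing notes. They ran from 9.48 to 26442, and the value distributions of the arrays were close but not identical. The lower quartile of an array lay between 20.8 and 23.6. The values carry no detection calls, so a group mean near that level is not shown to be above background, and a fold from it depends on the pseudocount. Signal over background, and the number of arrays, limit the precision.

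Values were transformed as log2 of the intensity plus 1, so that fold changes are ratios of intensity plus 1. Of 22930 probe sets, 19415 carried exactly 1 gene symbol; 125 that named several genes, 3292 that named none and 98 spike-in or control probe sets with a symbol were left out of the gene tests. Each gene was represented by its brightest probe set, which gave 11940 genes, of which 4507 had more than 1 probe set. A reference table served for names alone: 11874 symbols were matched by gene identifier and 0 changed.

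All 12 group means were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 23 residual and 5.5 prior degrees of freedom). Contrasts compared each treatment with DMSO of the same time, the combination with each single agent, the ATRA by VPA interaction at each time (the combination minus both single-agent changes), DMSO at 24 h and at 72 h with DMSO at 6 h, and each treatment effect at 72 h with that at 6 h, which makes 23 contrasts. P-values were adjusted by Benjamini-Hochberg over the 11940 genes within each contrast, with a threshold of 0.05. Errors are standard errors of the log2 change from this fit.

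The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each treatment against DMSO, the 6 largest rises and the 6 largest falls among genes past 0.05 whose treated arrays all lay on the same side of every DMSO array of that time. It also took the 4 members of each described list with the largest absolute log2 change, and for the other contrasts the 5 largest rises and the 5 largest falls past 0.05. Always taken up were CYP26A1, RARB, DHRS3, CRABP2, RET, NTRK2, MYCN, TH, DBH, CDKN1A, HDAC1, HDAC2, NEFM, GAP43 and MKI67, and the text gives each change of these against DMSO that passed and some that did not. Other genes the rule always takes up were not analysed here.

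The 25 gene lists were retinoid response, HOX genes, neuronal cytoskeleton and neurite, synapse and neuronal excitability, neuroendocrine secretory, neurotrophin receptors, noradrenergic identity, mesenchymal and substrate-adherent, Schwann and glial, epithelial, haematopoietic, DNA replication, G2 and mitosis, CDK inhibitors and antiproliferative, MYC targets and ribosome biogenesis, histone genes, histone deacetylases and acetyltransferases, reported HDAC inhibitor responsive, metallothioneins, sterol synthesis, amino acid and ER stress response, immediate early, MHC class I and interferon, apoptosis, and BMP, TGF-beta and Notch readouts. Of 607 genes on the lists, 538 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 575 tests, and again with an estimated correlation. Of the 207 list tests called with the preset correlation, 63 were called with the estimated one. Counts of members past the threshold are given over all genes, and those adjusted over the list alone stand beside them where they differ.

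The procedure was tested on simulated data with 50 genes planted per size. Noise was normal and independent, with a single SD per gene for all arrays. Arrays that stand apart and unequal spreads between groups are therefore not covered. At ATRA against DMSO at 72 h, where DMSO has 2 arrays, 98% of genes planted at a log2 change of 1 were called. The share was 36% for those at 0.5 and 58% for those at -0.5. For the interaction at 24 h these shares were 90%, 22% and 32%. Calls among unplanted genes were 3 for ATRA at 72 h and 5 for the interaction at 24 h.

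The alternatives tried were a replicate block, a fit of only the arrays compared, leaving out the lowest 33.3% of genes by mean value, the mean of all probe sets of a gene, an intensity trend with a robust prior, array weights, a second quantile normalization, a pseudocount of 32, and leaving out each array in turn. Those chosen after seeing the data were the 3'/5' control ratio as a covariate, leaving out the 5 arrays whose ratio exceeded that of their group's others by more than 0.4, leaving out DMSO 24 h replicate 1 or ATRA plus VPA 6 h replicate 1 for lists and named genes, and quantile normalization for the list tests. The 3'/5' ratio is the mean of the GAPDH and ACTB control probe set log2 ratios on an array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.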

Results

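The series was set up to find an expression signature of neuroblastoma differentiation for a screen, and its arrays follow BE(2)-C cells under 2 agents and their combination. BE(2)-C carries extra copies of MYCN, and retinoic acid is known to bring neuroblastoma cells to extend neurites. There were 3 arrays in each of 11 groups and 2 in DMSO at 72 h. Median intensity per array ran from 53.15 to 58.89, apart from DMSO 24 h replicate 1 at 43.63. Mean correlation of an array with its own group across genes was 0.9892 to 0.9978, lowest in DMSO 24 h replicate 1. That array stood apart, with a residual SD of 0.286 against 0.113 to 0.210 in the others and 218 genes at least 1 log2 unit below the mean of the other arrays of its group. ATRA plus VPA 6 h replicate 1 had 56 such genes, and no other array more than 25.

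The 3'/5' ratio of the GAPDH and ACTB controls, a sign of RNA and labelling quality, differed between groups. Its log2 mean at 6 h was 0.27 ± 0.09 (SD, n = 3) with DMSO and 0.20 to 0.44 in the treated groups. At 24 h it was 1.05 ± 0.26 (SD, n = 3) with DMSO, 0.89 with ATRA, 1.60 with VPA and 0.97 with the combination. At 72 h it was 1.06 ± 0.17 (SD, n = 2) with DMSO, 1.09 with VPA, 1.36 with the combination and 1.82 ± 0.17 (SD, n = 3) with ATRA.

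**Figure D1:**
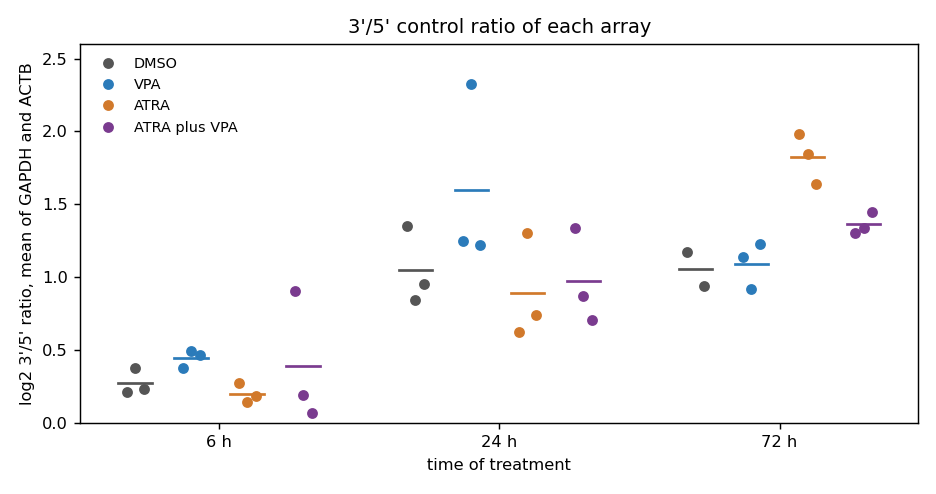
Log2 3'/5' ratio of the GAPDH and ACTB control probe sets (vertical axis) for each of the 35 arrays (points), by treatment and time, with lines at the group means. The means lie between 0.20 and 0.44 at 6 h, and ATRA at 72 h has the highest mean, 1.82.

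ATRA against DMSO at 6 h asks which genes responded first to the retinoid. The largest rise was in PRKCH, a protein kinase C, at 9.48-fold (log2 change 3.24 ± 0.13, SE, n = 3 per group, adjusted p = 1.6e-16). HTR2B, a serotonin receptor, rose 3.16-fold. CRABP2, which carries retinoic acid to its nuclear receptor, rose 3.07-fold (1.62 ± 0.17, adjusted p = 1.7e-07). RET, the receptor kinase for GDNF family ligands, rose 2.17-fold (1.11 ± 0.15, adjusted p = 8.3e-06). KCTD12, a subunit of GABA-B receptors, was 2.14-fold lower and the deacetylase HDAC9 1.78-fold lower (adjusted p = 1.1e-05). The retinoid-degrading enzyme CYP26A1 had a log2 change of 0.46 ± 0.17 (adjusted p = 0.32) and RARB, a retinoic acid receptor, one of 0.02. RARB had mean intensities of 17.2 with DMSO and 17.5 with ATRA, below the lower quartile of the arrays. A response of RARB could therefore have gone unseen. MYCN was 1.20-fold lower (-0.27 ± 0.07, adjusted p = 0.041), a call lost without any 1 of the 6 arrays and by the mean of its probe sets (adjusted p = 0.68).

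Of 21 measured retinoid response genes 7 rose, 0 fell and 14 did not pass at 6 h, with 9 up adjusted over the list alone; examples are CRABP2, RET and the plasminogen activator PLAT at 2.09-fold. The list was called (adjusted p = 5.7e-15, and 2.5e-05 with an estimated correlation). HOXD4 rose 1.92-fold (log2 change 0.94, or 0.59 with a pseudocount of 32), while 21 of the 22 HOX genes did not pass (2 up adjusted over the list alone, list adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation). Among immediate early genes, 3 rose, 1 fell and 15 did not pass (4 up and 2 down adjusted over the list alone); EGR1 and DUSP6, a phosphatase of ERK kinases, each rose 2.16-fold, and IER3 2.30-fold. That list had adjusted p = 0.0064, and adjusted p = 0.14 with an estimated correlation. Of 16 CDK inhibitors and antiproliferative genes 3 rose, CCNG2 at 1.79-fold and GADD45A at 1.68-fold among them (list adjusted p = 0.002, and adjusted p = 0.1 with an estimated correlation). The 33 MYC target and ribosome biogenesis genes had a median log2 change of -0.12 with 1 fall (6 adjusted over the list alone, list adjusted p = 7.9e-06, and adjusted p = 0.13 with an estimated correlation). In all, 193 genes passed, 123 up and 70 down, 29 of them by at least 2-fold. The count was 109 without DMSO 6 h replicate 2, 120 without DMSO replicate 3, and 122, 121 and 123 without ATRA 6 h replicates 1, 2 and 3.

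ATRA against DMSO at 24 h asks how the response had grown after 1 day. HTR2B rose 23.4-fold (4.55 ± 0.14, SE, n = 3 per group, adjusted p = 1.9e-20), PRKCH 21-fold and CRABP2 16.9-fold (4.08 ± 0.17). The CYP26 enzymes, which oxidise retinoic acid, had now risen: CYP26B1 13.5-fold and CYP26A1 8.46-fold, from a mean intensity of 22.7, near the lower quartile of the arrays, to 199. With a pseudocount of 32 the log2 changes were 3.89 for HTR2B, 3.68 for PRKCH, 2.51 for CYP26B1 and 2.08 for CYP26A1, in place of 4.55, 4.39, 3.75 and 3.08. CDKN1A, an inhibitor of cyclin-dependent kinases, rose 5.03-fold (2.33 ± 0.22, adjusted p = 2.5e-09), and RET 4.81-fold. KCTD12 was 6.92-fold lower, the glutamate transporter SLC1A3 3.12-fold lower and HDAC9 2.29-fold lower. MYCN had a log2 change of -0.11 (adjusted p = 0.29), RARB one of -0.26 (0.077) and NEFM, a neurofilament, one of 0.15 (0.097). RARB was near or below the lower quartile of the arrays, at mean intensities of 21.9 with DMSO and 18.1 with ATRA. DHRS3, a retinal reductase, rose 1.99-fold, tyrosine hydroxylase (TH) 1.62-fold (adjusted p = 0.033) and HDAC2 1.15-fold (0.03), and GAP43, a growth cone protein, was 1.21-fold lower. The calls of TH and HDAC2 were lost without DMSO 24 h replicate 1, and that of GAP43 by the mean of its probe sets.

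Cell division genes fell at 24 h with ATRA: of 36 DNA replication genes 26 fell and 10 did not pass (29 down adjusted over the list alone), with CDC7 1.85-fold lower and E2F1 1.58-fold lower. Of 36 genes of G2 and mitosis 27 fell and 9 did not pass (32 down adjusted over the list alone), among them TOP2A at 1.55-fold lower and MKI67, a proliferation marker, at 1.39-fold lower. Both lists were called (adjusted p = 4.4e-19 and 6.9e-20, and 0.0061 and 0.0086 with an estimated correlation). Of the retinoid response genes 11 rose, 1 fell and 9 did not pass (11 up and 3 down adjusted over the list alone, adjusted p = 3.7e-08, and 0.00074 with an estimated correlation). Of 17 neuroendocrine secretory genes 9 rose, 2 fell and 6 did not pass (adjusted p = 0.00059, and 0.017 with an estimated correlation); the rises included the peptide galanin (GAL) at 2.84-fold, VGF at 2.82-fold and SCG5 at 2.94-fold. Of 19 immediate early genes 10 rose and 0 fell (11 up adjusted over the list alone, adjusted p = 2e-08, and 0.0042 with an estimated correlation), with IER3 up 12-fold (3.58, or 2.84 with a pseudocount of 32) and DUSP6 up 11.6-fold.

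Further groups moved at 24 h with ATRA by the preset correlation alone. Of 29 neuronal cytoskeleton and neurite genes 12 rose and 4 fell (13 and 5 adjusted over the list alone), with DPYSL3 up 3.17-fold and the RNA-binding ELAVL4 up 2.69-fold (adjusted p = 0.0049, and adjusted p = 0.21 with an estimated correlation). Of 25 noradrenergic identity genes 11 rose and 1 fell, with the vesicular transporter SLC18A1 up 2.35-fold and the transcription factor PHOX2A up 2.02-fold (adjusted p = 9e-04, and adjusted p = 0.19 with an estimated correlation). DBH, which makes noradrenaline, rose 1.61-fold. Of HOX genes 8 rose, HOXD4 at 3.47-fold and HOXD1 at 2.33-fold among them (adjusted p = 0.0022, and adjusted p = 0.094 with an estimated correlation). Of 36 mesenchymal and substrate-adherent genes 11 rose and 2 fell, with fibronectin (FN1) up 5.73-fold (adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). Metallothioneins, which bind metals, had 4 falls among 8, MT2A at 1.81-fold lower (adjusted p = 0.00047, and adjusted p = 0.092 with an estimated correlation). In all, 2213 genes passed, 1493 up and 720 down; after a second quantile normalization the split was 1094 up and 1224 down. Without DMSO 24 h replicate 1 it was 850 and 808. A fit of the 6 arrays compared alone called 718 genes, and by the mean of all probe sets the log2 change of FN1 was 1.67 in place of 2.52 and that of HOXD1 0.57 in place of 1.22.

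ATRA against DMSO at 72 h asks what the cells expressed after 3 days. CYP26B1 was 31.2-fold higher (4.96 ± 0.15, SE, n = 3 and 2, adjusted p = 2.1e-20) and CYP26A1 26.6-fold higher (4.73 ± 0.19), from a mean intensity of 22.0 to 612; with a pseudocount of 32 their log2 changes were 3.64 and 3.58. CALCB, which encodes a calcitonin gene-related peptide, rose 25-fold, the neuronal protease PRSS12 23.7-fold, and STMN4, a regulator of microtubules, 18.2-fold (log2 changes with a pseudocount of 32 of 3.56 for CALCB and 3.35 for STMN4, in place of 4.65 and 4.19). KCTD12 was 8.18-fold lower and PLPPR4, a phospholipid phosphatase-related membrane protein, 6.75-fold lower. CRABP2 rose 13.2-fold, CDKN1A 2.56-fold, DHRS3 2.15-fold (1.11, or 0.64 with a pseudocount of 32) and NEFM 1.26-fold. MKI67 fell 1.73-fold, to a mean intensity of 759 from 1310. MYCN was 1.30-fold lower (-0.38 ± 0.08, adjusted p = 0.00037); the mean of its probe sets gave a log2 change of -1.29 and a second quantile normalization -0.21. RARB rose 1.75-fold (0.81, or 0.25 by the mean of its probe sets and 0.37 with a pseudocount of 32) and GAP43 1.22-fold, a call lost by the mean of its probe sets. DBH was 1.41-fold lower (adjusted p = 0.0018, and 0.054 with the 3'/5' ratio as a covariate).

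Of the 36 genes of G2 and mitosis 35 fell at 72 h with ATRA and 1 did not pass, by a median log2 change of -0.66 (AURKB 2.27-fold lower, CDC25B 2.07-fold lower). Of 36 DNA replication genes 31 fell, by a median of -0.64 (CDC7 2.68-fold lower, MCM10 2.64-fold lower). Both lists were called (adjusted p = 2.1e-18 and 1.4e-14, and 0.012 and 0.019 with an estimated correlation). The retinoid response list had 12 rises and 0 falls (adjusted p = 5.6e-10, and 0.00026 with an estimated correlation) and HOX genes 8 rises, HOXD4 at 4.67-fold, and 0 falls (adjusted p = 4.8e-05, and 0.028 with an estimated correlation). Neuroendocrine secretory genes had 9 rises, 3 falls and 5 that did not pass (10 and 3 adjusted over the list alone, adjusted p = 7e-05, and 0.0059 with an estimated correlation); GAL rose 6.06-fold and SCG5 4.42-fold, while chromogranin A (CHGA) was 2.36-fold lower. Immediate early genes had 9 rises and 1 fall (adjusted p = 1.3e-05, and 0.02 with an estimated correlation), with DUSP6 up 19.1-fold and EGR1 up 4.33-fold.

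Neuronal cytoskeleton and neurite genes had 14 rises, 4 falls and 11 that did not pass at 72 h with ATRA (adjusted p = 1.5e-05, and adjusted p = 0.056 with an estimated correlation): doublecortin (DCX) rose 5.83-fold and DPYSL3 4.56-fold, while the neurofilament NEFH was 2.38-fold lower. Synapse and neuronal excitability genes had 9 rises and 3 falls of 31 (adjusted p = 0.0042, and adjusted p = 0.15 with an estimated correlation), with the sodium channel SCN3A up 3.63-fold and the vesicle protein SYNGR3 up 3.43-fold. MYC target and ribosome biogenesis genes had 24 falls and 0 rises of 33 (29 falls adjusted over the list alone), with ODC1 1.86-fold lower (adjusted p = 3.4e-08, and adjusted p = 0.063 with an estimated correlation). Noradrenergic identity genes had 8 rises and 5 falls and the list was not called; the noradrenaline transporter SLC6A2 rose 2.65-fold (log2 change 1.40, or 0.84 by the mean of its probe sets), and the vesicular transporter SLC18A2 was 3.85-fold and HAND1 2.5-fold lower. Neurotrophin receptors had 3 rises and 1 fall of 11 (3 and 2 adjusted over the list alone), with RET up 2.21-fold and NTRK2 at a log2 change of 0.22 (adjusted p = 0.27). NTRK2 passed in no comparison with DMSO. HDAC1 was 1.81-fold lower. In all, 3690 genes passed, 1277 up and 2413 down, and 2409 without DMSO 72 h replicate 2; after a second quantile normalization the split was 1551 up and 1836 down, with 29 mitosis and 16 MYC target genes still lower. The 3'/5' ratio was higher in these ATRA arrays than in DMSO, 1.82 against 1.06.

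**Figure D2:**
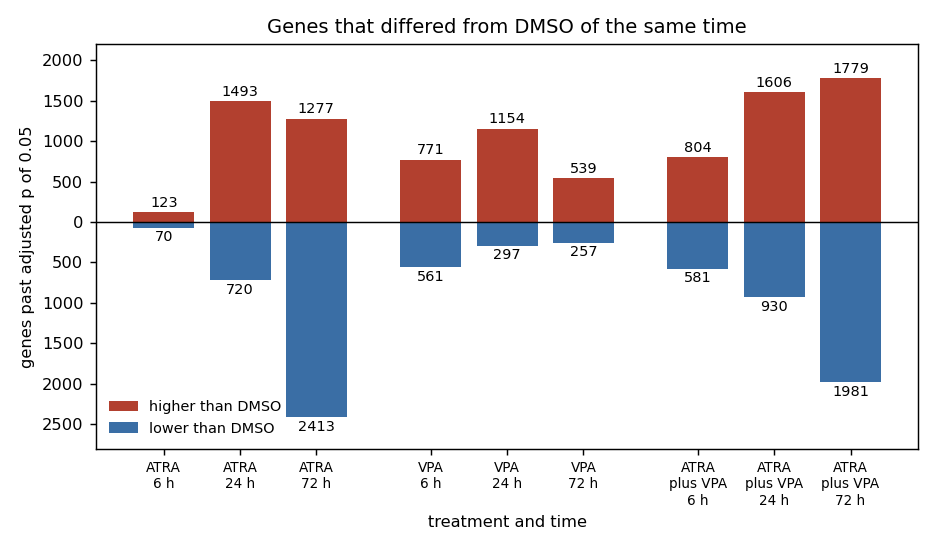
Number of genes past an adjusted p of 0.05 against DMSO of the same time (vertical axis), by treatment and time (horizontal axis); bars above 0 count genes that were higher and bars below 0 genes that were lower. ATRA goes from 123 higher and 70 lower at 6 h to 1277 and 2413 at 72 h, and VPA has 771 and 561 at 6 h; after a second quantile normalization ATRA at 72 h has 1551 and 1836.

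VPA against DMSO at 6 h asks for the early response to the deacetylase inhibitor. CXADR, the coxsackievirus and adenovirus receptor, rose 5.04-fold (2.33 ± 0.14, SE, n = 3 per group, adjusted p = 6.6e-12), the palmitoyltransferase ZDHHC11 3.94-fold and the transcription factor BATF3 3.40-fold. PRDM10 was 3.15-fold lower (-1.66 ± 0.14, adjusted p = 2.6e-09), and UBTF, which drives transcription of ribosomal RNA genes, 2.77-fold lower. Synaptic vesicle genes SYNGR3 and RAB3A rose 3.00-fold and 2.39-fold; in the synapse and neuronal excitability list 6 rose, 1 fell and 24 did not pass (7 up and 1 down adjusted over the list alone, adjusted p = 0.021, and adjusted p = 0.24 with an estimated correlation). Of 16 histone deacetylase and acetyltransferase genes 4 fell, 0 rose and 12 did not pass (adjusted p = 0.049, and adjusted p = 0.38 with an estimated correlation): KAT5 was 2.13-fold lower, HDAC9 1.65-fold, CREBBP 1.47-fold and EP300 1.32-fold. CRABP2 had a log2 change of 0.50 ± 0.17 (adjusted p = 0.055) and MYCN one of -0.07 (0.64). CDKN1A rose 1.79-fold (0.84 ± 0.22, adjusted p = 0.01), a call lost without DMSO 6 h replicate 3 or VPA 6 h replicate 1. By the mean of all probe sets the log2 change of PRDM10 was -0.95 and that of CREBBP -0.33, and with a pseudocount of 32 that of SYNGR3 was 0.94, in place of -1.66, -0.55 and 1.58.

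Of 25 noradrenergic identity genes 5 fell, 1 rose and 19 did not pass at 6 h with VPA (8 down adjusted over the list alone): MAB21L1 was 1.71-fold and the sympathetic transcription factor ISL1 1.68-fold lower, and GCH1, which makes a cofactor of catecholamine synthesis, rose 1.70-fold (list adjusted p = 0.0033, and adjusted p = 0.24 with an estimated correlation). Of DNA replication genes 7 fell and 1 rose (9 and 1 adjusted over the list alone); MCM5 was 1.46-fold lower and cyclin E1 (CCNE1) rose 2.16-fold (list adjusted p = 0.00036, and adjusted p = 0.28 with an estimated correlation). The MYC target list had 1 fall (0 adjusted over the list alone) and a median log2 change of -0.11 (adjusted p = 0.0057, and adjusted p = 0.36 with an estimated correlation). Of 24 apoptosis genes 4 rose and 1 fell (7 up and 2 down adjusted over the list alone), with APAF1, the core of the apoptosome, up 2.09-fold (1.06, or 0.40 by the mean of its probe sets); the list was not called. In all, 1332 genes passed, 771 up and 561 down, 94 of them by at least 2-fold. None of the list calls at this time held with an estimated correlation.

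VPA against DMSO at 24 h asks what differed after 1 day. EPB41L2, a membrane skeleton protein, rose 4.94-fold (2.30 ± 0.20, SE, n = 3 per group, adjusted p = 1.9e-09), SCN3A 3.8-fold and CXADR 3.47-fold. CRABP2 rose 3.08-fold (1.62 ± 0.17, adjusted p = 6.5e-08), while CYP26A1 had a log2 change of 0.09 and CDKN1A one of 0.32 (adjusted p = 0.38). HDAC1 rose 1.33-fold (adjusted p = 0.0076) and GAP43 1.21-fold (0.0027). The call of HDAC1 was lost without DMSO 24 h replicate 1 or either of VPA 24 h replicates 1 and 2, and that of GAP43 by the mean of its probe sets. SLC18A1 was 2.55-fold lower, LGR5, a Wnt pathway receptor, 2.46-fold lower and the histone gene H2BC12 1.82-fold lower (adjusted p = 3e-07). Sterol synthesis genes fell: 6 of 17 fell, 0 rose and 11 did not pass (7 down adjusted over the list alone, adjusted p = 6.6e-08, and 0.023 with an estimated correlation), with INSIG1 1.62-fold and HMGCS1 1.58-fold lower. By the mean of all probe sets the log2 change of EPB41L2 was 1.49, that of LGR5 -0.86 and that of HMGCS1 -1.20, in place of 2.30, -1.30 and -0.66. With a pseudocount of 32 EPB41L2 had 1.69, and SCN3A 1.31 in place of 1.93.

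Of 36 mesenchymal and substrate-adherent genes 13 rose and 0 fell at 24 h with VPA, with the collagen COL5A1 up 2.95-fold and FN1 2.19-fold (adjusted p = 0.00048, and adjusted p = 0.1 with an estimated correlation). Of 24 MHC class I and interferon genes 7 rose and 0 fell (8 and 1 adjusted over the list alone), HLA-C at 1.93-fold among them (adjusted p = 0.032, and adjusted p = 0.26 with an estimated correlation). Of 20 histone genes 4 fell and 0 rose (adjusted p = 0.0012, and adjusted p = 0.2 with an estimated correlation); several histone probe sets match paralogs. The MYC target list had 1 fall (0 adjusted over the list alone, adjusted p = 0.00099, and adjusted p = 0.28 with an estimated correlation). The genes of G2 and mitosis had 4 rises and 0 falls. In all, 1451 genes passed, 1154 up and 297 down; after a second quantile normalization the split was 829 and 605. Without DMSO 24 h replicate 1 it was 742 and 613. The count was 943 without VPA 24 h replicate 2, the array with the highest 3'/5' ratio (2.33), and 250 in a fit of the 6 arrays compared alone.

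VPA against DMSO at 72 h asks what differed after 3 days. With VPA 206 genes were called higher and 34 lower at all 3 times, and 19 in opposite directions at 6 h and 72 h. IFI16, an interferon-inducible DNA sensor, rose 6.27-fold (2.65 ± 0.17, SE, n = 3 and 2, adjusted p = 4.6e-12, or 1.96 with a pseudocount of 32), lumican (LUM), a matrix proteoglycan, 5.51-fold, HTR2B 4.48-fold and the Wnt antagonist DKK1 3.96-fold. From 6 h to 72 h the log2 effect of VPA grew by 2.59 for IFI16, 2.35 for LUM and 2.82 for HTR2B, so these were late changes. DKK1 itself was lower in DMSO at 72 h than at 6 h. SLC18A1 was 2.67-fold lower and the histone gene H2AC18 2.32-fold lower (adjusted p = 2e-04). CRABP2 rose 2.91-fold and GAP43 1.32-fold. MKI67 had a log2 change of -0.24 (adjusted p = 0.18), MYCN one of 0.04 (0.87), CDKN1A one of -0.08 (0.94) and CYP26A1 one of -0.16 (0.76). H2AC18 had a log2 change of -1.21, or -0.76 by the mean of its probe sets.

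Of mesenchymal and substrate-adherent genes 13 rose, 1 fell and 22 did not pass at 72 h with VPA (adjusted p = 6.1e-09, and 0.0076 with an estimated correlation), with LUM, FN1 at 3.01-fold and COL3A1 at 2.42-fold. With the mean of all probe sets the log2 changes of FN1 and COL3A1 were 1.00 and 0.78 in place of 1.59 and 1.27. Of MHC class I and interferon genes 5 rose and 0 fell (7 up adjusted over the list alone, adjusted p = 1.3e-05, and 0.021 with an estimated correlation), with HLA-C up 2.58-fold and HLA-E 2.45-fold. Of histone genes 7 fell, 0 rose and 13 did not pass (9 down adjusted over the list alone, adjusted p = 4.6e-08, and 0.028 with an estimated correlation), H2BC21 at 1.99-fold lower among them. Immediate early genes had 5 rises and 0 falls (6 rises adjusted over the list alone), EGR1 at 3.06-fold (adjusted p = 0.0034, and adjusted p = 0.11 with an estimated correlation). The sterol list had 4 falls, with ACAT2 1.64-fold lower (adjusted p = 5.1e-05, and adjusted p = 0.088 with an estimated correlation). DNA replication genes had 2 falls and a median log2 change of -0.20, and those of G2 and mitosis 1 fall (0 adjusted over the list alone) and a median of -0.21 (adjusted p = 1.1e-05 and 2.1e-05, and adjusted p = 0.17 and 0.22 with an estimated correlation). In all, 796 genes passed, 539 up and 257 down; the count was 390 without DMSO 72 h replicate 1 and 317 without replicate 2.

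The combination against DMSO at 6 h asks what both agents did together early. RAB20, a small GTPase, rose 6.17-fold (2.63 ± 0.16, SE, n = 3 per group, adjusted p = 5.3e-12, or 1.86 with a pseudocount of 32), LRRC32 4.60-fold, CXADR 3.91-fold and IER3 3.69-fold. CRABP2 rose 3.35-fold, RET 2.08-fold and CDKN1A 1.78-fold (adjusted p = 0.011), the last a call lost without DMSO 6 h replicate 3 or ATRA plus VPA 6 h replicate 1. MYCN was 1.26-fold lower (adjusted p = 0.0014, and 0.062 by the mean of its probe sets). CYP26A1 rose 1.53-fold (adjusted p = 0.016), a call lost with a pseudocount of 32 (adjusted p = 0.088). HDAC9 was 2.89-fold lower (-1.53 ± 0.11, adjusted p = 1.2e-10), and the sympathetic transcription factors GATA3 and ISL1 each 2.01-fold lower. Of retinoid response genes 7 rose and 0 fell (adjusted p = 0.00036, and 0.017 with an estimated correlation). DNA replication genes had 6 falls and 1 rise (10 and 1 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.34 with an estimated correlation), and the MYC target list 6 falls and 0 rises (10 falls adjusted over the list alone), NOP56 at 1.39-fold lower (adjusted p = 2e-05, and adjusted p = 0.15 with an estimated correlation). In all, 1385 genes passed, 804 up and 581 down, or 574 and 560 without ATRA plus VPA 6 h replicate 1.

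The combination against DMSO at 24 h had the largest rise in HTR2B, at 50.6-fold (5.66 ± 0.14, SE, n = 3 per group, adjusted p = 4.8e-23), with PRKCH at 29.8-fold, CALCB at 19.9-fold, CYP26A1 at 15.4-fold and CRABP2 at 15.2-fold. CALCB and CYP26A1 had low levels with DMSO. With a pseudocount of 32 the log2 changes were 4.98 for HTR2B, 4.18 for PRKCH, 3.34 for CALCB and 2.85 for CYP26A1, in place of 5.66, 4.90, 4.32 and 3.95. RET rose 3.82-fold, CDKN1A 3.21-fold, DHRS3 2.91-fold (1.54, or 0.99 with a pseudocount of 32), DBH 1.45-fold and RARB 1.37-fold, the last a call lost by the mean of its probe sets. MYCN was 1.16-fold lower (adjusted p = 0.029), a call lost without DMSO 24 h replicate 3 or ATRA plus VPA 24 h replicate 1. KCTD12 was 4.98-fold and LGR5 3.54-fold lower. Retinoid response genes had 12 rises and 0 falls (adjusted p = 3.3e-11, and 0.00014 with an estimated correlation). Mesenchymal and substrate-adherent genes had 14 rises and 0 falls (15 rises adjusted over the list alone), FN1 at 6.38-fold (adjusted p = 4.5e-06, and 0.031 with an estimated correlation). Of 36 DNA replication genes 23 fell and 0 rose (25 down adjusted over the list alone, adjusted p = 2.8e-13, and 0.023 with an estimated correlation), and of 17 sterol synthesis genes 8 fell and 0 rose (9 down adjusted over the list alone), INSIG1 at 2.02-fold lower (adjusted p = 1.6e-06, and 0.042 with an estimated correlation). Of MYC target genes 18 fell and 0 rose (21 down and 1 up adjusted over the list alone), ODC1 at 1.71-fold lower (adjusted p = 7.4e-09, and adjusted p = 0.052 with an estimated correlation). Of the genes of G2 and mitosis 7 fell, 1 rose and 28 did not pass (adjusted p = 0.0094, and adjusted p = 0.46 with an estimated correlation), and MKI67 had a log2 change of -0.11 (adjusted p = 0.46). In all, 2536 genes passed, 1606 up and 930 down; after a second quantile normalization the split was 1315 and 1482. It was 1028 and 1154 without DMSO 24 h replicate 1. A fit of the 6 arrays compared alone called 788, and by the mean of its probe sets INSIG1 had a log2 change of -0.60 in place of -1.01.

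The combination against DMSO at 72 h asks what the 2 agents gave together after 3 days. CALCB rose 94.6-fold (6.56 ± 0.12, SE, n = 3 and 2, adjusted p = 4.7e-26), GDF15, a stress-induced cytokine, 46.2-fold, CYP26A1 32.6-fold and STMN4 22.1-fold. CALCB had a mean log2 value of 4.66 with DMSO, near the lower quartile of the arrays. With a pseudocount of 32 the log2 changes were 5.43 for CALCB, 4.46 for GDF15, 3.85 for CYP26A1 and 3.61 for STMN4, in place of 6.56, 5.53, 5.03 and 4.46. By the mean of its probe sets GDF15 had a log2 change of 2.75 in place of 5.53. FN1 rose 10.2-fold, SYNGR3 9.39-fold, SCN3A 9.37-fold, and monoamine oxidase A (MAOA) 5.64-fold. With a pseudocount of 32 the log2 changes were 2.45 for SYNGR3, 2.64 for SCN3A and 1.91 for MAOA, in place of 3.23, 3.23 and 2.5. CRABP2 rose 14.9-fold, CDKN1A 3.38-fold, DHRS3 2.93-fold (1.55, or 0.95 with a pseudocount of 32), RET 2.34-fold and GAP43 1.24-fold. DBH was 1.44-fold lower. RARB rose 3.61-fold (1.85 ± 0.12, or 0.40 by the mean of its probe sets and 1.00 with a pseudocount of 32). PLPPR4 was 7.40-fold and H2AC18 4.19-fold lower, MKI67 2.31-fold lower (adjusted p = 7e-11), and MYCN 1.26-fold lower (-0.33 ± 0.08, or -1.10 by the mean of its probe sets). The mean of all probe sets gave log2 changes of 1.28 for MAOA and -1.36 for H2AC18.

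All 36 measured genes of G2 and mitosis fell at 72 h with the combination, by a median log2 change of -0.81 (CDC20 2.56-fold lower), and 35 of 36 DNA replication genes fell, by a median of -0.91 (MCM4 3.48-fold lower). Both lists were called (adjusted p = 1.1e-23 and 1.4e-23, and 0.0045 and 0.0037 with an estimated correlation). Of MYC target genes 28 of 33 fell (29 adjusted over the list alone, adjusted p = 2.2e-12, and 0.02 with an estimated correlation). Retinoid response genes had 12 rises (13 adjusted over the list alone, adjusted p = 4.7e-09, and 0.00042 with an estimated correlation), neuroendocrine secretory genes 10 rises and 2 falls (adjusted p = 0.00029, and 0.012 with an estimated correlation), mesenchymal and substrate-adherent genes 17 rises and 1 fall (adjusted p = 7.7e-06, and 0.034 with an estimated correlation) and immediate early genes 13 rises and 1 fall (adjusted p = 1.4e-05, and 0.021 with an estimated correlation). Synapse and neuronal excitability genes had 14 rises and 2 falls (adjusted p = 0.00072, and adjusted p = 0.088 with an estimated correlation) and neuronal cytoskeleton and neurite genes 14 rises and 4 falls (15 and 5 adjusted over the list alone, adjusted p = 1e-04, and adjusted p = 0.088 with an estimated correlation). The 28 reported HDAC inhibitor responsive genes had 12 rises and 5 falls (12 and 6 adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.1 with an estimated correlation). The list includes CDKN1A, whose mean log2 value at 72 h was 7.03 with DMSO, 6.95 with VPA and 8.39 with ATRA. Rises of this list with the combination therefore cannot be assigned to deacetylase inhibition. Histone genes had 9 falls and 0 rises (adjusted p = 0.0068, and adjusted p = 0.28 with an estimated correlation). In all, 3760 genes passed, 1779 up and 1981 down.

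**Figure D3:**
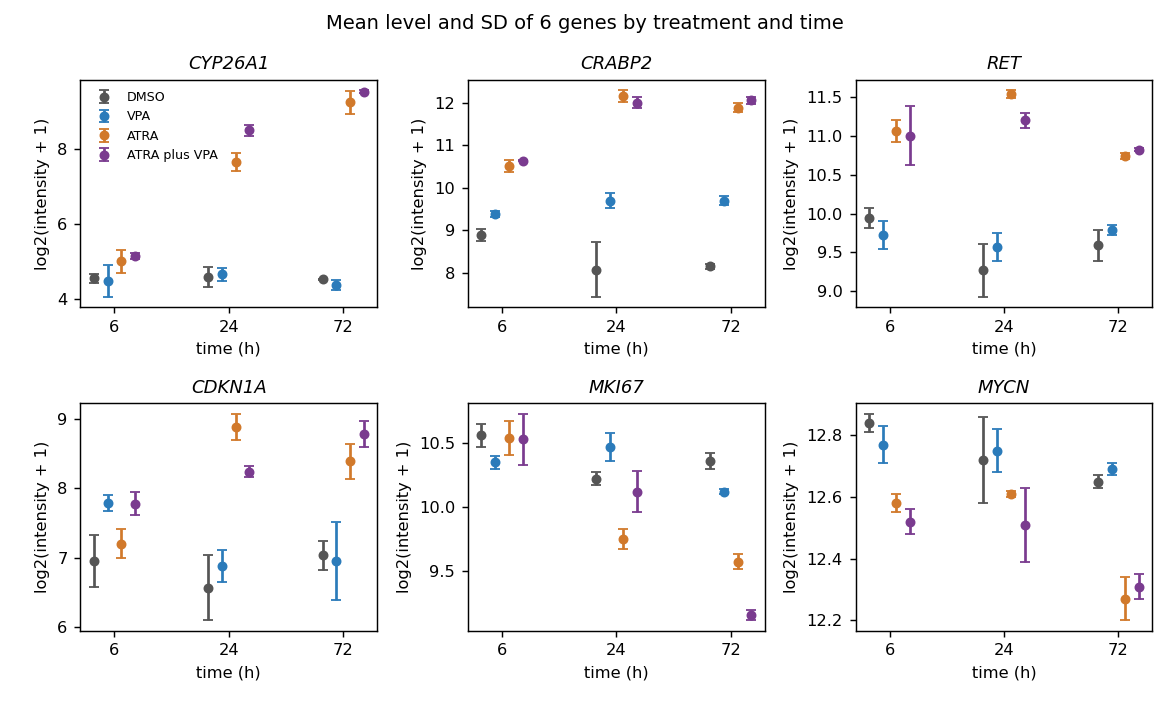
Mean log2 of intensity plus 1 (vertical axis) of CYP26A1, CRABP2, RET, CDKN1A, MKI67 and MYCN at 6 h, 24 h and 72 h (horizontal axis) in each treatment, with error bars of 1 SD over 3 arrays (2 for DMSO at 72 h). CYP26A1 goes from a mean intensity of 22.0 with DMSO to 612 with ATRA and 749 with the combination at 72 h, and MKI67 from 1310 to 759 and 567.

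**Figure D4:**
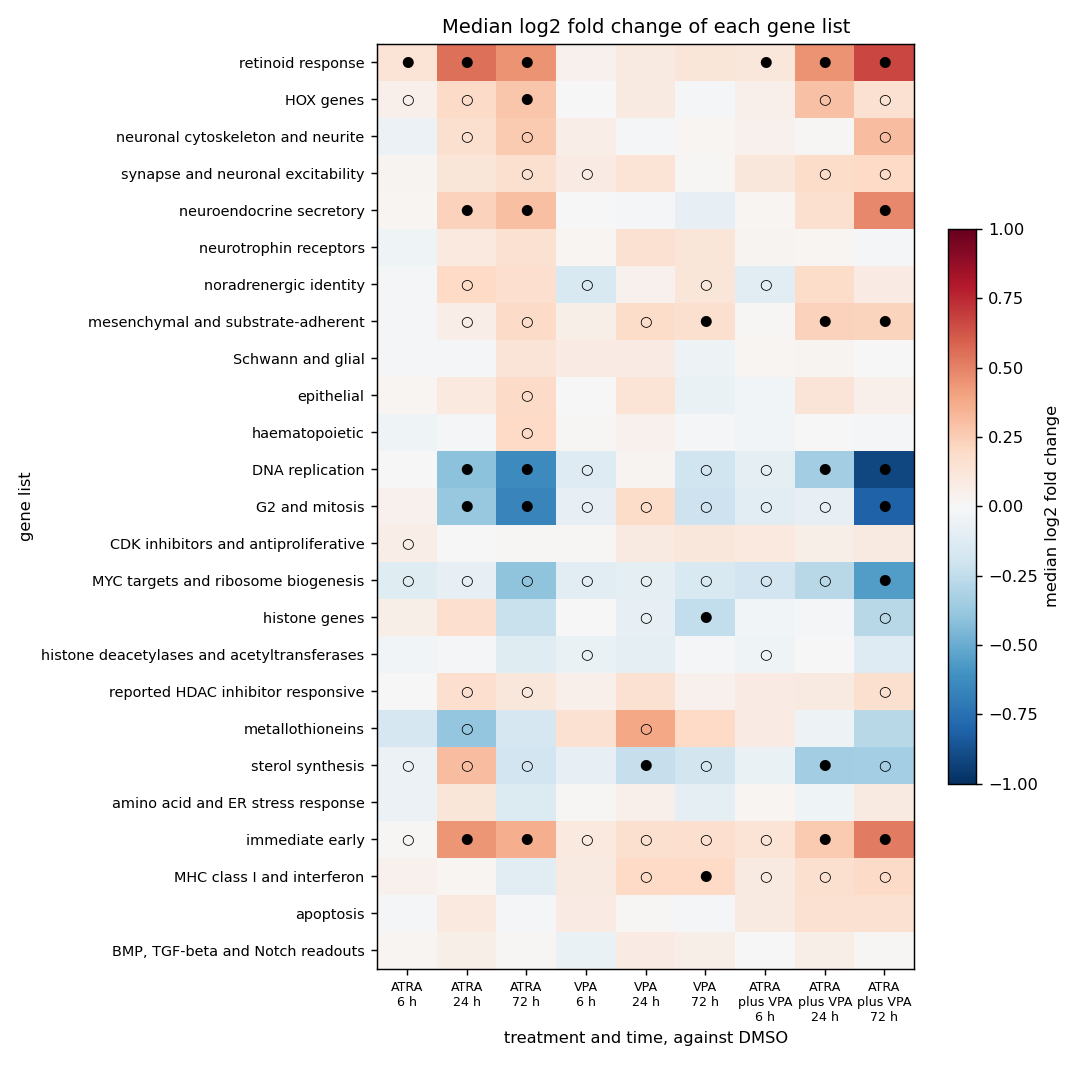
Median log2 change against DMSO (colour, red higher and blue lower) of the 25 gene lists (vertical axis) in the 9 treatment and time comparisons (horizontal axis); filled circles mark list calls that held with an estimated correlation and open circles those with the preset correlation alone. DNA replication and G2 and mitosis are bluest at 72 h with the combination, with medians of -0.91 and -0.81.

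Comparing the combination with each single agent asks what the second agent added. At 6 h, adding VPA to ATRA raised CXADR 5.23-fold and SLITRK5, a neuronal membrane protein, 3.50-fold (1.81 ± 0.13, SE, n = 3 per group, adjusted p = 1.1e-10), while PRKCH was 2.92-fold lower than with ATRA alone (adjusted p = 3e-09). DNA replication genes had 7 falls and 1 rise against ATRA (8 and 1 adjusted over the list alone, adjusted p = 0.00058, and adjusted p = 0.29 with an estimated correlation), and genes of G2 and mitosis 7 falls and 0 rises (8 falls adjusted over the list alone, adjusted p = 0.00087, and adjusted p = 0.34 with an estimated correlation). With a pseudocount of 32 CXADR had a log2 change of 1.79 in place of 2.39. Adding ATRA to VPA raised PRKCH 5.68-fold (2.51, or 1.81 with a pseudocount of 32) and HTR2B 2.52-fold, and HDAC9 was 1.75-fold and GATA3 1.66-fold lower. Retinoid response genes had 5 rises and 0 falls against VPA (8 up adjusted over the list alone, adjusted p = 2.2e-12, and 8.3e-05 with an estimated correlation). The combination differed from ATRA in 1429 genes (851 up, 578 down, or 566 and 472 without ATRA plus VPA 6 h replicate 1) and from VPA in 68 (54 up, 14 down).

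At 24 h, adding VPA to ATRA gave lower sterol synthesis and neuroendocrine genes and higher mitosis and MHC class I genes. Of 17 sterol synthesis genes 14 were lower than with ATRA and 0 higher (15 lower adjusted over the list alone), by a median log2 difference of -0.66 (adjusted p = 1.7e-20, and 0.00045 with an estimated correlation): HMGCS1 was 2.35-fold lower (-1.23 ± 0.10, SE, n = 3 per group), INSIG1 2.15-fold and IDI1 1.87-fold lower. Of 17 neuroendocrine secretory genes 8 were lower and 1 higher (adjusted p = 1.3e-05, and 0.0039 with an estimated correlation), with GAL 3.21-fold lower (adjusted p = 5.1e-15). Of genes of G2 and mitosis 14 were higher and 0 lower (22 higher adjusted over the list alone, adjusted p = 2.8e-15, and 0.021 with an estimated correlation), TOP2A at 1.38-fold. Of MHC class I and interferon genes 7 were higher and 0 lower (8 higher adjusted over the list alone), HLA-C at 1.87-fold (adjusted p = 0.00017, and 0.048 with an estimated correlation). CALCB was 4.89-fold and CYP26A1 1.82-fold higher (adjusted p = 0.00092), and SLC18A1 2.78-fold lower. Of 11940 genes 1133 differed (580 up, 553 down), 718 without ATRA 24 h replicate 3 and 737 in a fit of the 6 arrays compared alone.

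Adding ATRA to VPA at 24 h raised PRKCH 33.7-fold (5.08 ± 0.13, SE, n = 3 per group, adjusted p = 6.6e-22, or 4.28 with a pseudocount of 32), HTR2B 21-fold and CYP26A1 14.5-fold (log2 change 3.86, or 2.82 with a pseudocount of 32), and KCTD12 was 5.58-fold lower. Retinoid response genes had 11 rises and 0 falls against VPA (adjusted p = 8.4e-16, and 2.5e-05 with an estimated correlation), and DNA replication genes 19 falls and 0 rises (22 falls adjusted over the list alone, adjusted p = 6.6e-14, and 0.021 with an estimated correlation). Genes of G2 and mitosis had 16 falls and 0 rises (19 falls adjusted over the list alone, adjusted p = 7e-08, and adjusted p = 0.11 with an estimated correlation). The count was 1417 (612 up, 805 down), 896 without ATRA plus VPA 24 h replicate 3 and 834 in a fit of the 6 arrays compared alone.

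At 72 h, adding VPA to ATRA raised FGF13, an intracellular FGF homologous factor, 4.29-fold (2.10 ± 0.13, SE, n = 3 per group, adjusted p = 2.4e-12), LUM 4.17-fold and neuropeptide Y (NPY) 2.16-fold. GDF15 was 7.15-fold higher, with a log2 difference of 2.84, or 1.44 by the mean of its probe sets. PNMT, which makes adrenaline, was 2.42-fold and H2BC21 2.37-fold lower (PNMT -1.27, or -0.79 with a pseudocount of 32). Of MHC class I and interferon genes 13 were higher and 0 lower, by a median log2 difference of 0.29 (adjusted p = 0.00019, and 0.049 with an estimated correlation), HLA-C at 2.72-fold and HLA-B at 2.09-fold. DNA replication genes had 16 lower and 0 higher (20 lower adjusted over the list alone), by a median of -0.25 (adjusted p = 7.1e-10, and adjusted p = 0.053 with an estimated correlation), E2F1 at 1.63-fold lower, and genes of G2 and mitosis 12 lower and 0 higher (13 lower adjusted over the list alone, adjusted p = 3.4e-05, and adjusted p = 0.23 with an estimated correlation). Mesenchymal and substrate-adherent genes had 16 higher and 1 lower (17 and 2 adjusted over the list alone, adjusted p = 0.00055, and adjusted p = 0.1 with an estimated correlation). In all 2478 genes differed, 1738 up and 740 down, or 1269 and 1305 after a second quantile normalization; the count was 1639 without ATRA plus VPA 72 h replicate 3.

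Adding ATRA to VPA at 72 h raised CALCB 69.4-fold (6.12 ± 0.11, SE, n = 3 per group, adjusted p = 1.5e-26) and CYP26A1 36.5-fold (log2 changes of 5.20 and 3.92 with a pseudocount of 32, in place of 6.12 and 5.19), and PLPPR4 was 7.64-fold lower. All 36 genes of G2 and mitosis were lower than with VPA alone and 34 of 36 DNA replication genes (35 adjusted over the list alone), with 0 higher (adjusted p = 1e-24 and 2.1e-24, and 0.0039 and 0.0033 with an estimated correlation). Of MYC target genes 22 of 33 were lower (25 adjusted over the list alone, adjusted p = 3.9e-10, and 0.034 with an estimated correlation). Neuronal cytoskeleton and neurite genes had 15 higher and 1 lower (15 and 3 adjusted over the list alone, adjusted p = 2.9e-06, and 0.038 with an estimated correlation), HOX genes 10 higher and 0 lower (adjusted p = 0.00011, and 0.034 with an estimated correlation) and neuroendocrine secretory genes 10 higher and 2 lower (adjusted p = 2.4e-05, and 0.0042 with an estimated correlation). In all, 3072 genes differed, 1469 up and 1603 down.

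The interaction asks where the combination departed from the sum of the 2 single-agent changes on the log2 scale. At 24 h the neuropeptide GAL fell short of the sum by a log2 difference of -1.76 ± 0.11 (SE, n = 3 per group, adjusted p = 2e-11), the water channel AQP3 by -2.20 ± 0.21 (-0.85 by the mean of its probe sets, adjusted p = 1.2e-07) and EGR1 by -1.41 ± 0.19 (adjusted p = 3.9e-05). PPARG, a nuclear receptor, exceeded it by 1.38 ± 0.20 (0.85 with a pseudocount of 32, adjusted p = 0.00015) and CALCB by 0.96 ± 0.16 (adjusted p = 0.00075). Of the 88 genes past the threshold 79 were negative and 9 positive, and among the 79 both single agents had a positive change in 69. Both single changes and the interaction use the same DMSO arrays. Low DMSO values alone would make both changes positive and the interaction negative, so the 69 are no separate evidence. Lists with negative interactions were sterol synthesis at a median of -0.41 (1 negative member, and 12 adjusted over the list alone, adjusted p = 1.3e-08, and 0.019 with an estimated correlation), immediate early at -0.34 (4 negative members, and 7 adjusted over the list alone, adjusted p = 1.1e-08, and 0.0039 with an estimated correlation) and neuroendocrine secretory at -0.25 (3 negative members, and 7 adjusted over the list alone, adjusted p = 4.1e-05, and 0.0048 with an estimated correlation). The count was 56 without DMSO 24 h replicate 1, 231 without DMSO replicate 3, 55 without VPA 24 h replicate 2 and 55 without ATRA plus VPA 24 h replicate 2. After a second quantile normalization it was 14 positive and 54 negative, 18 in a fit of the 12 arrays of that time alone, 411 with array weights and 51 without the arrays of high 3'/5' ratio.

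At 72 h GDF15 exceeded the sum by a log2 difference of 2.93 ± 0.21 (SE, n = 3, 3, 3 and 2, adjusted p = 2.7e-10, or 1.51 by the mean of its probe sets), the calcium-binding SCGN by 2.49 ± 0.16 and KCTD12 by 2.05 ± 0.15. The homeobox gene SHOX2 fell short by -1.63 ± 0.16 (-0.84 by the mean of its probe sets, adjusted p = 1.3e-07), CRABP2 by -1.37 ± 0.25 and EGR1 by -1.13 ± 0.20. Of 229 genes 156 were positive and 73 negative, and the combination lay above both single agents in 114 of the 156. Selection for a positive interaction favours such genes, so the 114 are no separate evidence. The combination was called higher than DMSO in 71 of the 156. After a second quantile normalization the split was 128 positive and 163 negative. The count was 752 with array weights, 353 with a pseudocount of 32 and 885 without the arrays of high 3'/5' ratio. None of the arrays left out for their ratio was at 72 h, so the count of 885 reflects only a change in the spread that all groups share. It was 97 and 95 without DMSO 72 h replicates 1 and 2, 147 without VPA 72 h replicate 2, 366 without ATRA 72 h replicate 3 and 144 without ATRA plus VPA 72 h replicate 3. At 6 h limma called 0 genes, and 1 without ATRA plus VPA 6 h replicate 1. An unadjusted p under 0.05 was met by 282 of 11940 genes, less than the share of 0.05 that chance alone gives. Across genes, the sum of the single-agent changes correlated with the combination at r of 0.87, 0.89 and 0.87 at 6 h, 24 h and 72 h; genes are not independent replicates.

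ATRA and VPA shared the direction of 36 genes at 6 h, 376 at 24 h and 397 at 72 h, of which 28, 330 and 230 were up, and moved 31, 167 and 95 genes in opposite directions. Lists drawn independently would share 7.9, 144.3 and 57.6 rises and 3.3, 17.9 and 51.9 falls. Both comparisons use the same DMSO arrays, and simulated data with no treatment effect shared 1.87, 10.7 and 2.89 genes on average, with highest values of 185, 618 and 134 in 100 draws. The covariance of the 2 log2 changes across genes was 0.00198, 0.018 and 0.0438, against means of 0.00696, 0.0107 and 0.0122 in the simulated data. The highest simulated covariances were 0.036, 0.05 and 0.0428, so only the value at 72 h exceeded them, and narrowly. The r was 0.05, 0.20 and 0.39 against 0.44, 0.45 and 0.57. DMSO could not be divided into separate sets of at least 2 arrays. The shared count was 20, 23 and 17 at 6 h without DMSO replicates 1, 2 and 3, 227 and 709 at 24 h without DMSO replicates 1 and 3, and 175 and 142 at 72 h without DMSO replicates 1 and 2. Of the genes that rose with ATRA at 24 h and at 72 h there were 588, and 494 fell at both; with VPA these were 374 and 71, and with the combination 1106 and 695.

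The DMSO arrays were compared between times, where time in culture and any processing day cannot be told apart. At 24 h against 6 h the insulin-like growth factor binding protein IGFBP5 rose 2.57-fold (1.36 ± 0.10, SE, n = 3 per group, adjusted p = 4e-10), the quinone reductase NQO1 2.24-fold, AKR1C3 2.15-fold and INSIG1 2.15-fold. With the mean of all probe sets the log2 changes of IGFBP5, NQO1 and INSIG1 were 0.60, 0.53 and 0.45 in place of 1.36, 1.16 and 1.10; AKR1C paralogs are close in sequence. At 72 h against 6 h SCGN rose 3.37-fold and AKR1C1 3.12-fold, while DKK1 was 4.83-fold lower (-2.27 ± 0.11, n = 2 and 3, adjusted p = 3.2e-14) and RAMP1, a subunit of calcitonin family receptors, 3.88-fold lower. BMP, TGF-beta and Notch readouts had 8 falls and 0 rises of 21 at 72 h (8 and 1 adjusted over the list alone, adjusted p = 8.1e-06, and 0.0037 with an estimated correlation). DNA replication genes had 11 falls and 1 rise at 24 h (16 and 2 adjusted over the list alone, adjusted p = 0.00037, and adjusted p = 0.28 with an estimated correlation) and 13 falls and 1 rise at 72 h (17 and 2 adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.14 with an estimated correlation). Amino acid and ER stress response genes had 9 falls and 0 rises of 24 at 24 h (11 falls adjusted over the list alone, adjusted p = 1.3e-05, and adjusted p = 0.068 with an estimated correlation). At 24 h 1814 genes passed (620 up, 1194 down; 1017 and 1017 after a second quantile normalization). The count was 958 and 1204 without DMSO 6 h replicates 1 and 3, 697 without DMSO 24 h replicate 1, 118 in a fit of the 6 arrays alone and 186 with the 3'/5' ratio as a covariate, which was 0.27 at 6 h and 1.05 at 24 h. At 72 h 1263 passed (606 up, 657 down), with 806 without DMSO 6 h replicate 1, 411 and 547 without DMSO 72 h replicates 1 and 2, 2115 in a fit of the 5 arrays alone and 438 with the ratio as a covariate.

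The effect of ATRA grew between 6 h and 72 h for CALCB by a log2 change of 4.64 ± 0.16 (SE, n = 3, 3, 3 and 2, adjusted p = 2.8e-18), CYP26B1 by 4.58 ± 0.21 and CYP26A1 by 4.27 ± 0.26, or by 3.56, 3.49 and 3.36 with a pseudocount of 32, and for DHRS3 by 1.06 ± 0.28 (adjusted p = 0.0085). Of genes of G2 and mitosis 34 of 36 had a lower effect at 72 h and of DNA replication genes 28, with 0 higher (35 and 31 adjusted over the list alone, adjusted p = 6.4e-22 and 7.2e-16, and 0.0059 and 0.013 with an estimated correlation). Neuronal cytoskeleton and neurite genes had 12 higher and 3 lower (15 and 3 adjusted over the list alone, adjusted p = 2.5e-07, and 0.023 with an estimated correlation). The effect of VPA on HTR2B went from a log2 change of -0.66 at 6 h (adjusted p = 0.0011) to 2.16 at 72 h, a difference of 2.82 ± 0.20; that on LUM grew by 2.35 ± 0.15 and that on ZDHHC11 fell by 1.93. With VPA, mesenchymal and substrate-adherent genes had 6 higher and 0 lower (10 higher adjusted over the list alone, adjusted p = 3.4e-07, and 0.019 with an estimated correlation). The effect of the combination grew for CALCB by 6.22 ± 0.16 (5.25 with a pseudocount of 32). These differences passed in 2069 genes for ATRA (665 up, 1404 down; 881 and 968 after a second quantile normalization), 239 for VPA (148 up, 91 down) and 2032 for the combination (943 up, 1089 down). Without DMSO 72 h replicate 2 the count was 1285 for ATRA and 143 for VPA, and without DMSO 72 h replicate 1 it was 126 for VPA. A fit of only the arrays compared called 377 for VPA.

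Against DMSO, all 3 treated arrays lay beyond every DMSO array in 2302 genes at 6 h with ATRA, 3579 with VPA and 3410 with the combination, where chance puts 10% of the 11940 genes. These counts were 3230, 2547 and 3244 at 24 h, and 6422, 4947 and 6621 at 72 h, where chance puts 20%.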

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

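The tests of shared histone probe sets and of S phase below, and the fits with the 3'/5' ratio, were chosen only after the result was seen. A difference between times singled out 3 counts: the effect of ATRA differed between 72 h and 6 h in 2069 genes, that of VPA in 239 and that of the combination in 2032. A difference between treatment contexts singled out the interaction, with 88 genes at 24 h and 229 at 72 h. Signal in probe sets with no named gene, outside the main comparisons, singled out 3 more counts at 72 h against DMSO. Control probe sets and those with identifiers starting MC or RAE230 were left out here. Of the 2864 that remained 494 passed with ATRA (188 up, 306 down), 42 with VPA (27 up, 15 down) and 452 with the combination (216 up, 236 down).

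Most of the 88 interaction genes at 24 h were negative (79), and in 69 of these both single agents had a positive change. A ceiling of the intensity scale is argued against: the median log2 value of the combination over the 79 genes was 8.18, where one above 13 was set in advance to favour a ceiling and one below 11 to count against it, and the highest was 12.34. The DMSO array with low median intensity stays open, since without it 80.4% of the calls were negative (45 genes), close to the 80% set in advance to count against it. A biological saturation of shared targets may also account for those 69 and was not tested apart from these. Low values in the DMSO arrays, which both single changes and the interaction use, would give the same pattern. The 69 therefore do not point to saturation. In 100 regroupings of the arrays 21 gave as many interaction genes at 24 h, the highest 2544 against the real 88, so chance is not excluded there, although regroupings that mix treatments carry their effects; at 6 h the real count of 0 fixed the outcome (100 of 100, the highest 940), which decides nothing.

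More genes fell (2413) than rose (1277) with ATRA at 72 h. The 3'/5' ratio, highest in these arrays, stays open. With the ratio as a covariate 69.5% of calls were falls (1934 genes), so a linear adjustment did not remove the excess. The slope of that adjustment comes from differences within groups. Between ATRA and DMSO at 72 h the ratio differed together with the treatment (1.82 against 1.06), so the fit cannot separate them. A narrower distribution of values on the ATRA 72 h arrays is a candidate explanation for the imbalance: after a second quantile normalization 54.2% of calls were falls (1836 genes). A true excess of repressed genes, with cell division genes among them, remains open, because quantile normalization would remove it too.

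Histone genes fell with VPA at 72 h (7 of 20), while 2 of 36 DNA replication genes fell. The cRNA was primed from oligo-dT, so histone transcripts without a poly(A) tail would largely be missed. Probe sets shared between histone paralogs stay open: 1 of the 7 falling genes, H2BC12, has a probe set with no letter code for shared sequence, and 6 have one with it. Fewer cells in S phase stays open as well. The log2 change with ATRA minus that with VPA had a median of 0.13 over the histone list and -0.42 over the DNA replication list. The SE of the mean over the histone list members was 0.09. Members are not independent replicates, so this SE does not measure the spread between arrays. A direct effect of deacetylase inhibition on histone genes may apply and was not tested.

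For the comparisons of 3 arrays with 3, the 10 regroupings are too few for a share under 0.05; the real grouping was the 1 with the highest count each time. Against DMSO, the real count and the highest other were 193 and 0 for ATRA, 1332 and 2 for VPA, and 1385 and 3 for the combination at 6 h, and 2213 and 6, 1451 and 206, and 2536 and 92 at 24 h. For the combination against ATRA they were 1429 and 0 at 6 h, 1133 and 1 at 24 h, and 2478 and 2 at 72 h. Against VPA they were 68 and 2, 1417 and 309, and 3072 and 0, and for DMSO at 24 h against 6 h 1814 and 1.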

How the results depend on the processing

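The 3'/5' ratio as a covariate, leaving out the 5 arrays of high ratio or either of 2 single arrays, and quantile normalization of the list tests were chosen after seeing the data; the other alternatives were planned. Signal near background limits the small changes, and leaving out a DMSO 72 h array leaves a lone sample that is assumed to vary like the other groups. Of 1550 called results of named genes 338 lost their call in at least 1 fit without an array and 1212 kept it in all. No list call turned direction under any alternative run, but some were lost and others gained. Without the genes of lowest mean value 29 list calls were lost and 6 gained. These counts were 26 and 8 after quantile normalization, and 22 and 12 by the mean of all probe sets. They were 16 and 8 without the arrays of high ratio, and 12 and 6 with the ratio as a covariate. They were 8 and 5 without DMSO 24 h replicate 1, and 10 and 2 without ATRA plus VPA 6 h replicate 1. The replicate block called 184 genes for ATRA at 6 h, 3774 for ATRA at 72 h, 78 and 262 for the interaction at 24 h and 72 h, 1125 for DMSO at 72 h against 6 h and 209 list tests; no total moved by over 1.5 times. Under this replicate block nothing pairs: arrays of the same number had mean residual correlations of -0.044, -0.003 and 0.025 at 6 h, 24 h and 72 h, and 2 of 12, 3 of 12 and 5 of 11 arrays matched their own number best. No total count moved by over 1.5 times with the mean of all probe sets or after quantile normalization. Counts of 1 direction did after quantile normalization. Falls went from 297 to 605 for VPA, 720 to 1224 for ATRA and 930 to 1482 for the combination at 24 h, 740 to 1305 for the combination against ATRA at 72 h, and 14 to 27 against VPA at 6 h. Lower effects of VPA at 72 h against 6 h went from 91 to 143, rises in DMSO at 24 h from 620 to 1017, positive interactions at 24 h from 9 to 14 and negative ones at 72 h from 73 to 163.

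With array weights the counts were 549 for ATRA, 2135 for VPA and 2431 for the combination at 6 h, 3431, 2414 and 4473 at 24 h, and 1741 for VPA at 72 h. They were 2416 for the combination against ATRA and 196 against VPA at 6 h, 2513 and 2571 at 24 h, 3, 411 and 752 for the interaction at 6 h, 24 h and 72 h, 3210 and 3012 for DMSO at 24 h and 72 h against 6 h, and 697 and 3326 for the effects of VPA and the combination at 72 h against 6 h. With only the arrays compared, where fewer arrays set the spread, they were 718, 250 and 788 for ATRA, VPA and the combination at 24 h, 737 and 834 for the combination against ATRA and VPA at 24 h, 18 for the interaction at 24 h, 118 and 2115 for DMSO at 24 h and 72 h, and 377 for the VPA effect. The groups also varied unequally. Residual SDs of the arrays were 0.176 to 0.286 in DMSO at 24 h, 0.119 to 0.145 in DMSO at 6 h and 0.117 in DMSO at 72 h. In the main fit, counts against DMSO at 24 h thus rest on a spread pooled with groups of smaller spread. The interaction at 6 h had 1 gene without the lowest 33.3% of genes, 1 with the intensity trend and robust prior and 2 with a pseudocount of 32, which gave 353 at 72 h. With the 3'/5' covariate DMSO had 186 genes at 24 h and 438 at 72 h. Without the arrays of high ratio there were 296 for ATRA at 6 h, 163 for the combination against VPA at 6 h, 51 and 885 for the interaction at 24 h and 72 h, 2088 for DMSO at 72 h, 451 for the VPA effect, and overlaps of ATRA and VPA of 63, 184 and 640. The arrays left out belonged to the combination at 6 h and to the groups at 24 h. Counts that use none of these groups changed only through the spread that all groups share. The estimated correlation called 63 list tests. By the mean of all probe sets the log2 change reversed for NCAM1 with VPA at 24 h (-0.06), MYCN in the combination against VPA at 24 h (0.07), RB1 and HMGCS1 in DMSO at 24 h (-0.25 and -0.04), and UCP2 and HMGCS1 in DMSO at 72 h (-0.05 and -0.01). The cause was not tested.

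Leave-one-out counts ranged from 109 to 129 for ATRA, 929 to 1066 for VPA and 1010 to 1154 for the combination at 6 h; 1648 to 2685, 943 to 1801 and 2050 to 2735 at 24 h; and 2409 to 3755, 317 to 671 and 2781 to 3430 at 72 h. For the combination against ATRA they ranged from 995 to 1234, 718 to 1007 and 1639 to 2531, and against VPA from 49 to 79, 896 to 1609 and 2584 to 2665. For the interaction they ranged from 0 to 1, 55 to 231 and 95 to 366, for DMSO from 697 to 2439 at 24 h and 411 to 1024 at 72 h, and for the effects of ATRA, VPA and the combination from 1285 to 2244, 126 to 213 and 1469 to 2006. The overlap of ATRA and VPA ranged from 17 to 23, 227 to 709 and 142 to 175, and part of it may come from the DMSO arrays that both comparisons share.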

Other observations

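Several stress and signalling genes moved in lists that were not called against DMSO. Of 24 amino acid and ER stress response genes 7 rose and 6 fell with ATRA at 72 h (7 and 7 adjusted over the list alone), and 8 rose and 3 fell with the combination (8 and 4). The cystine transporter SLC7A11 rose 3.15-fold with either (log2 change 1.65 with ATRA, or 0.93 by the mean of its probe sets), and the glutathione-degrading enzyme CHAC1 2.49-fold with ATRA (log2 change 1.31 ± 0.16, SE, n = 3 and 2, adjusted p = 2.2e-07), while with VPA at 72 h 1 of the 24 rose and 0 fell (2 rises adjusted over the list alone). Of 21 BMP, TGF-beta and Notch readouts 5 rose and 6 fell with ATRA at 72 h (6 and 6 adjusted over the list alone), or 5 and 3 after a second quantile normalization; the Notch target HEY1 rose 2.5-fold and DLK1, a Notch ligand homolog, was 2.67-fold lower. With VPA at 72 h the Notch target HES1 rose 1.79-fold (0.84, or 0.50 by the mean of its probe sets) and SMAD7 was 1.78-fold lower. Of 24 apoptosis genes 5 rose and 1 fell with the combination at 72 h, with the death receptor TNFRSF10B up 8.46-fold (3.08 ± 0.20, or 1.10 by the mean of its probe sets and 2.10 with a pseudocount of 32) and the survival gene BCL2 up 3.81-fold (1.93 ± 0.14; by the mean of its probe sets 0.46).

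Of 16 histone deacetylases and acetyltransferases 4 fell and 1 rose with ATRA at 72 h, and 3 fell with the combination; HDAC2 had log2 changes of 0.09 with ATRA and 0.09 with the combination. Markers of other cell types moved in some members, and with the combination at 72 h 1779 of all 11940 genes rose. Of 10 Schwann and glial genes 1 rose with ATRA at 72 h (0 adjusted over the list alone), and 0 changed with VPA at any time. Of 14 epithelial genes 3 rose with the combination at 72 h, keratin KRT18 at 3.44-fold (1.78, or 1.18 with a pseudocount of 32). Of 15 haematopoietic genes 3 rose with the combination at 72 h, the actin-bundling LCP1 at 3.90-fold among them. Neurotrophin receptors had 1 rise and 3 falls with the combination at 72 h, with RET up 2.34-fold and GFRA2, a GDNF family co-receptor, 1.94-fold lower.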
